A study of Mus musculus with 6 samples.

How the data were processed

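ATAC-seq, which marks open chromatin by the cuts of the Tn5 transposase, was run on 6 libraries of primary mouse vascular smooth muscle cells. Per the labels' protocols, each assay used 50000 cells and a Tn5 reaction of 30 min, and cells were kept for 24 h after siRNA transfection. The labels put 3 libraries in a negative control group and 3 in a group given siRNA against Arid3a. Each of the 3 knockdown libraries received a different siRNA, so the spread within that group holds differences between siRNAs as well as between libraries. The labels do not say that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. An angiotensin II treatment is described in the labels without the libraries that received it, and it was not used as a factor.

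The submitters' processing notes name Bowtie2, Picard and MACS2 and the genome build mm10. Their versions, the parameters, the treatment of duplicate reads, any shift of reads to the Tn5 cut site and the control used for peak calling are not given in the sources used here. A missing shift would move each summit by a few bases and would change overlaps of whole peaks little, while kept duplicates would raise tag numbers and peak calls in libraries of low complexity. The deposited files hold 1 peak list per library, so replicates could be compared as separately called lists. For each peak, the authors' caller gave a position, a summit, a fold enrichment at the summit over the local background of the same library, and the −log10 p and −log10 q of the deposited peak. The deposited score was the −log10 q multiplied by 10 and cut to a whole number, as a comparison of those columns showed. The smallest −log10 q in the deposited lists lay just above 1.30 in each of the 6 lists, the value that a q cutoff of 0.05 leaves. Fold enrichment and −log10 q are the authors' own values per peak, scaled within a library. Apart from the estimates of tags and depth below, values of single peaks served only to describe, rank or filter peaks and regions. The median fold enrichment of each library was also among the numbers compared per library between the groups. Positions are given from 1 on mm10.

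Depth was not stated, and was estimated from the lists. The deposited fold and −log10 p of a peak together fix its number of tags at the summit and its local background, under the Poisson model of MACS2. A whole number of tags from 1 to 600 matched −log10 p within 0.001 for at least 99.996% of peaks in each library. The most frequent lowest background of a library, its shortest peak as fragment length and the mouse genome size that MACS2 uses by default gave an estimated total of tags. That genome size was assumed, since the submitters' setting is not given in the sources used here, so the estimates serve to rank libraries by depth. Estimated totals ran from 0.950 to 2.00 M tags (megatags). The median peak held 8 to 11 tags at its summit, which limits which weak peaks a list can contain. The recovered tags entered no test of single regions. Their median per library and the estimated totals were among the 7 numbers compared per library, and the totals ranked libraries by depth.

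The 6 lists held peaks on chromosomes 1 to 19, X and Y. Peaks of all libraries were merged where they overlapped by at least 1 base, and a library was counted as present in such a region where 1 of its peaks overlapped it. A region was called control-only when it was present in 3 of 3 control and 0 of 3 knockdown libraries, and knockdown-only in the opposite case. With 3 libraries against 3, no single region can reach an exact p below 0.1, so regions were counted and described rather than called significant.

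Gene positions came from a RefSeq gene table of assembly GRCm38.p6, the same assembly as mm10, which gives the start and end of each gene without its strand. The planned promoter windows around transcription start sites were therefore replaced by windows of 1000 bases on each side of both annotated ends of each of 21883 protein-coding genes, called gene ends below. A peak at a gene end may lie at the start or at the end of the transcript. For the same reason regions were assigned to the nearest protein-coding gene within 100 kb of the region midpoint, and not to the nearest start site. A peak in the gene-end window of a gene may thus lie in a region assigned to another gene. Exons, introns and UTRs were not told apart. As a check of the build, peaks were also moved by 200 kb, which lowered the share at gene ends from between 22.1% and 26.4% per library to between 5.80% and 5.93%. A planned comparison of transcription factor motifs needed genome sequence and was not analysed here.

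Numbers per library were compared by exact two-sided permutation tests over the 20 relabellings of the 6 libraries, whose smallest p is 0.1. Similarity was the Jaccard index, bases shared by 2 lists divided by bases in either. Its mean over pairs within groups minus that over pairs between groups was tested one-sided over the 10 splits of the 6 libraries into 3 and 3. Gene lists were tested by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment, for control-only and knockdown-only regions against all other regions assigned to a gene. A further Fisher's exact test, chosen after the data were examined, compared each list with all other protein-coding genes for gene-end peaks in 6 of 6 libraries. Regions and genes are not replicates, so both tests describe these 6 libraries. The 19 gene lists, the main tests and the rule for named genes were fixed before the data were examined. The 19 lists held 293 entries, all matched to the gene table by symbol, for 290 distinct genes. They covered contractile proteins, regulators of smooth muscle genes, collagens and synthetic matrix, elastic fibres, matrix proteases and inhibitors, inflammation, angiotensin and oxidant genes, TGF-β signalling, the cell cycle, apoptosis, AP-1, the ARID family and housekeeping genes. The other lists held markers of endothelial, leukocyte, fibroblast, epithelial, neural and Schwann, and chondro-osteogenic cells.

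The rule named, per direction, the 12 regions and the 8 gene ends with the highest value of the smallest −log10 q among the libraries that carried them, leaving out predicted genes without a descriptive symbol. It also named, per list, up to 3 members with a group-specific region, up to 3 members by list order with a gene-end peak in all 6 or none of the libraries, and Arid3a itself. Of the gene ends that the rule gave, 1 is not reported here. Alternatives were a −log10 q of at least 5, lists reduced to the 33248 best peaks of each library, presence only where peaks covered at least 50% of a region, windows around summits, up to 1 of 3 libraries allowed in the other group, a replicate block, and each library left out in turn. The gene-end windows, a gene-end window of 2500 bases and a comparison of the 4 deepest libraries were added after the data were examined.

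The code was tested on simulated data. All 200 regions seeded as control-only among 79547 were recovered, and a further 317 were control-only by chance, with presence drawn for each library without a group effect. Exact tag numbers came back for 99.99% of 17212 simulated peaks, and the 1 planted gene list was called with 0 unplanted lists called. The planted list was given a large excess of specific regions, so its call does not show what excess the real lists would need. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.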

Results

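Open chromatin was mapped by ATAC-seq in primary mouse vascular smooth muscle cells, the contractile cells of the arterial wall. The question was which accessible regions differ when Arid3a is knocked down by RNA interference. Arid3a encodes a DNA-binding protein of the AT-rich interaction domain family. There were 3 libraries from cells given a negative control and 3 from cells given siRNA against Arid3a, each with a different siRNA. The control libraries, replicates 1 to 3, held 51330, 33248 and 52091 peaks, and the knockdown libraries held 50543, 51279 and 41629. Estimated depth, in megatags (M tags), was 1.93, 0.950 and 2.00 M tags in the control libraries and 1.90, 1.98 and 1.19 M tags in the knockdown libraries. Control replicate 2 and knockdown replicate 3 were thus the shallowest of the 6 and had the shortest lists.

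**Figure D1:**
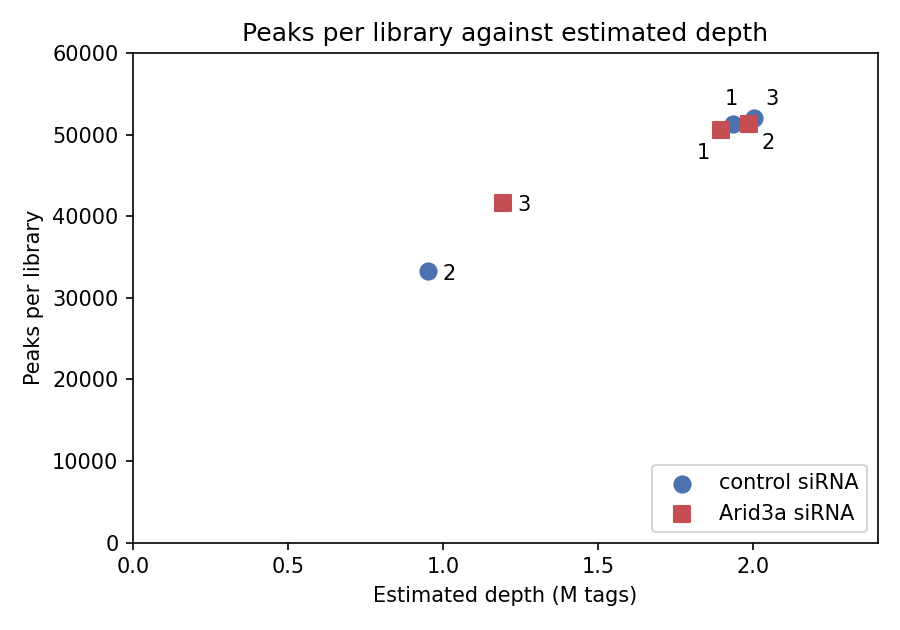
Number of peaks per library (vertical axis) against estimated depth in M tags (horizontal axis), 1 point per library, circles for the negative control and squares for Arid3a siRNA, with replicate numbers beside the points. Control replicate 2 (0.950 M tags, 33248 peaks) and knockdown replicate 3 (1.19 M tags, 41629 peaks) lie apart from the other 4 libraries, which hold 50543 to 52091 peaks.

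The Arid3a gene itself (chromosome 10, 79927043 to 79955018, mm10) carried open chromatin in both groups. Of 6 regions assigned to it, 2 were present in 6 of 6 libraries, both inside the gene, at 79934276 to 79934781 and at 79936754 to 79937481. In the first of these, the authors' fold enrichment was 9.27, 5.30 and 8.04 in control replicates 1 to 3 and 5.97, 6.67 and 6.38 in knockdown replicates 1 to 3. In the second it was 5.88, 6.09 and 7.65 in the control libraries and 7.75, 9.17 and 6.01 in the knockdown libraries. A weaker region at the lower-coordinate gene end, 79927221 to 79927839, was present in 3 of 3 control and 2 of 3 knockdown libraries and was not called in knockdown replicate 3, one of the shallowest libraries. RNA interference acts on the messenger RNA, so peaks at the gene do not show whether the knockdown worked in these libraries. Fold enrichments are scaled within each library, and those of single regions were not compared as change between libraries.

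**Figure D2:**
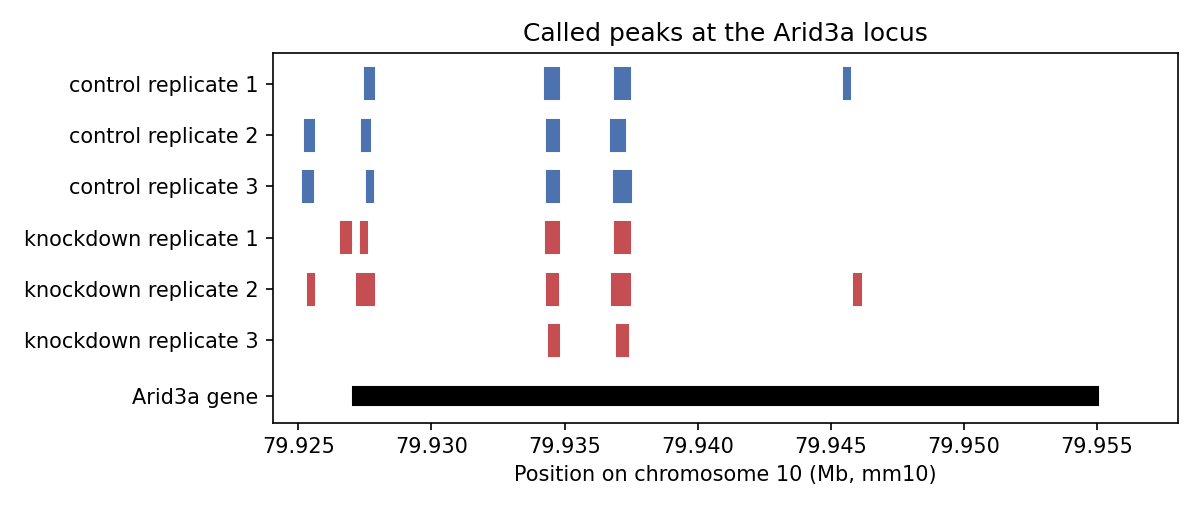
Called peaks in each of the 6 libraries along chromosome 10 (horizontal axis, position in Mb, mm10) around the Arid3a gene, drawn as a black bar from 79927043 to 79955018; coloured boxes are peaks, blue for the negative control and red for Arid3a siRNA. There are 2 positions inside the gene with a peak in all 6 libraries, and the region near the lower gene end lacks a peak in knockdown replicate 3.

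Across the genome, some smooth muscle genes and most housekeeping genes had an open gene end in every library of both groups. Gene ends of Acta2, Tagln and Smtn, which encode smooth muscle actin, transgelin and smoothelin, carried a peak in 6 of 6 libraries, with fold enrichments of 5.06 ± 0.963, 5.97 ± 1.16 and 7.59 ± 1.62 (SD, n = 6 libraries). No region was assigned to Tagln as the nearest gene, so the peak in its gene-end window lay in a region assigned to another gene. Of the 18 contractile genes, 7 had a gene-end peak in 6 of 6 libraries and 7, among them Myh11, Des and Synpo2, in 0 of 6, which did not set the list apart from all genes (odds ratio 1.11, two-sided Fisher's exact p = 0.811, adjusted p = 0.856). Gapdh, Hprt and Tbp were among 8 of 12 housekeeping genes with a gene-end peak in 6 of 6 libraries. The endothelial markers Pecam1, Cdh5 and Tie1 and the epithelial markers Cdh1, Epcam and Krt8 had a gene-end peak in 0 of 6 libraries. Of 21883 protein-coding genes, 7975 (36.4%) had a gene-end peak in 6 of 6 libraries and 9065 (41.4%) in 0 of 6. A gene without a gene-end peak can still hold other open regions. Of those assigned to Synpo2, 3 of 17 were present in 6 of 6 libraries, and of those assigned to Myh11, 0 of 4. For Pecam1, Cdh5 and Tie1 these were 1 of 8, 2 of 8 and 0 of 2. For Cdh1, Epcam and Krt8 they were 1 of 6, 1 of 7 and 0 of 3.

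The number of peaks and the covered length differed between the groups by less than the SD of either group. Control libraries held 45556 ± 10666 peaks and knockdown libraries 47817 ± 5372 (SD, n = 3; exact two-sided permutation p = 1). Covered length was 18.1 ± 4.29 Mb against 18.3 ± 2.17 Mb (SD, n = 3; exact two-sided permutation p = 0.9), and the mean peak width was 397 ± 9.98 and 382 ± 5.73 bases, a difference of −15.0 bases that exceeded both SDs (SD, n = 3; exact two-sided permutation p = 0.2). Gene ends took 23.6% ± 2.38 of control peaks and 22.8% ± 0.480 of knockdown peaks (SD, n = 3; exact two-sided permutation p = 0.9). This difference of −0.821 percentage points was below the control SD but above the knockdown SD. Control replicates 1 to 3 had 22.4%, 26.4% and 22.1%. Over the 7 numbers compared per library, each Benjamini-Hochberg adjusted p was 1, and 0.1 is the smallest unadjusted p that 3 libraries against 3 allow. Without control replicate 2, the difference, knockdown minus control, was −3893.5 peaks, −2.26 Mb and 0.548 percentage points at gene ends, each with the opposite sign. The difference in covered length was also negative without knockdown replicate 1 (−0.223 Mb), without knockdown replicate 2 (−0.639 Mb) and with lists of equal length (−0.279 Mb).

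Regions present in all 3 control libraries and in no knockdown library lay near Runx1, Hsph1, Plxna4, Kansl2 and Tnip1, among other genes. Runx1 encodes a transcription factor of blood cell development. Its region, at 92905633 to 92905906 on chromosome 16, lay 79.7 kb above the upper end of the gene. Among the control-only regions that the rule named, it was the best supported, with a smallest −log10 q of 8.51 and a fold enrichment of 10.3 ± 2.23 (SD, n = 3). The region of Hsph1, a heat shock protein gene, lay inside the gene at 149623944 to 149624296 on chromosome 5, with a fold enrichment of 7.26 ± 0.744 (SD, n = 3). The region of Plxna4, which encodes a semaphorin receptor, also lay inside its gene (chromosome 6, 32415689 to 32416154) and had a fold enrichment of 7.12 ± 0.673 (SD, n = 3). The region of Tnip1, whose product restrains NF-κB signalling, overlapped the upper gene end on chromosome 11, at 54962787 to 54963241. Tnip1 was not among the control-only gene ends, counted over both ends, so a knockdown library had a peak in its gene-end windows. The rule for named genes further gave Kansl2, Spats2l, Unc13c, Rbfox1 and Rbpms, each with the region inside the gene, Ppp5c 1.01 kb below its gene, H2-Oa 6.51 kb above and Acsl4 99.6 kb above. The smallest −log10 q of these 12 regions ran from 4.83 for Rbpms to 8.51 for Runx1. For each of them but Ppp5c it was the value of control replicate 2, the shallowest library. With lists of equal length the Ppp5c region was no longer control-only, nor were those of Unc13c and H2-Oa where peaks had to cover at least 50% of the region, nor that of Rbpms at a −log10 q of 5.

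Regions present in all 3 knockdown libraries and in no control library lay near Crabp2, Smim43, Gtpbp10, Tmem242 and Hmgn2. Crabp2 encodes a retinoic acid binding protein, and its region (chromosome 3, 87959429 to 87959715) lay 6.20 kb above the gene with a smallest −log10 q of 10.4 and a fold enrichment of 8.23 ± 1.04 (SD, n = 3). The region of Tmem242, 8.09 kb below the gene on chromosome 17 at 5402610 to 5402935, had a fold enrichment of 10.8 ± 2.50 (SD, n = 3). The region of Hmgn2, a nucleosome-binding protein gene, lay 24.2 kb below the gene on chromosome 4, at 133940411 to 133940705, with a fold enrichment of 8.50 ± 0.799 (SD, n = 3). Pappa2, which encodes a protease of insulin-like growth factor binding proteins, Apba1 and Bcas2 carried such a region inside the gene. For Smim43, Gtpbp10, Trim7 and Trhr it lay 3.32, 3.14, 3.20 and 2.22 kb outside the gene, for Cdc42ep1 8.33 kb and for Galnt15 81.4 kb. The smallest −log10 q of these 12 regions ran from 6.68 for Cdc42ep1 to 10.4 for Crabp2, and each of the 12 stayed knockdown-only where peaks had to cover at least 50% of the region. For each of them but Trim7, Galnt15 and Bcas2 the smallest value was that of knockdown replicate 3, the shallowest of its group.

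There were 236 control-only and 368 knockdown-only regions among 85174, or 0.277% and 0.432%. Regions present in 6 of 6 libraries numbered 20742 (24.4%), and 28560 (33.5%) were present in 1 library. The median peak of control-only and of knockdown-only regions held 6 tags at its summit, against 16.5 tags in regions present in 6 of 6 libraries. In all 3 libraries of their group, 12 control-only and 45 knockdown-only regions had a −log10 q of 5 or more. Other divisions of the same 6 libraries into 3 and 3 gave between 514 and 1257 group-specific regions, against 604 for the real one, and 5 of the 10 divisions, the real one included, gave at least 604. In the 5 other divisions that part control replicate 2 from knockdown replicate 3, the side of control replicate 2 always held fewer. It held 181 to 218 regions, against 327 to 367 on the other side. With only peaks of a −log10 q of 5 or more it held 66 to 84 against 158 to 190. The real division then held 75 against 170. An excess over the side of control replicate 2 thus also arose where sides mixed both groups. The excess of knockdown-only over control-only regions turned round without control replicate 2, with 1564 control-only and 475 knockdown-only regions. It stayed without control replicate 1 (607 and 1063) or 3 (540 and 1029), and without knockdown replicate 1 (589 and 885), 2 (658 and 834) or 3 (391 and 1562). In the 4 deepest libraries there were 2072 and 1870. Leaving a library out raises both counts by construction, since fewer libraries have to agree, and need not raise them equally.

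**Figure D3:**
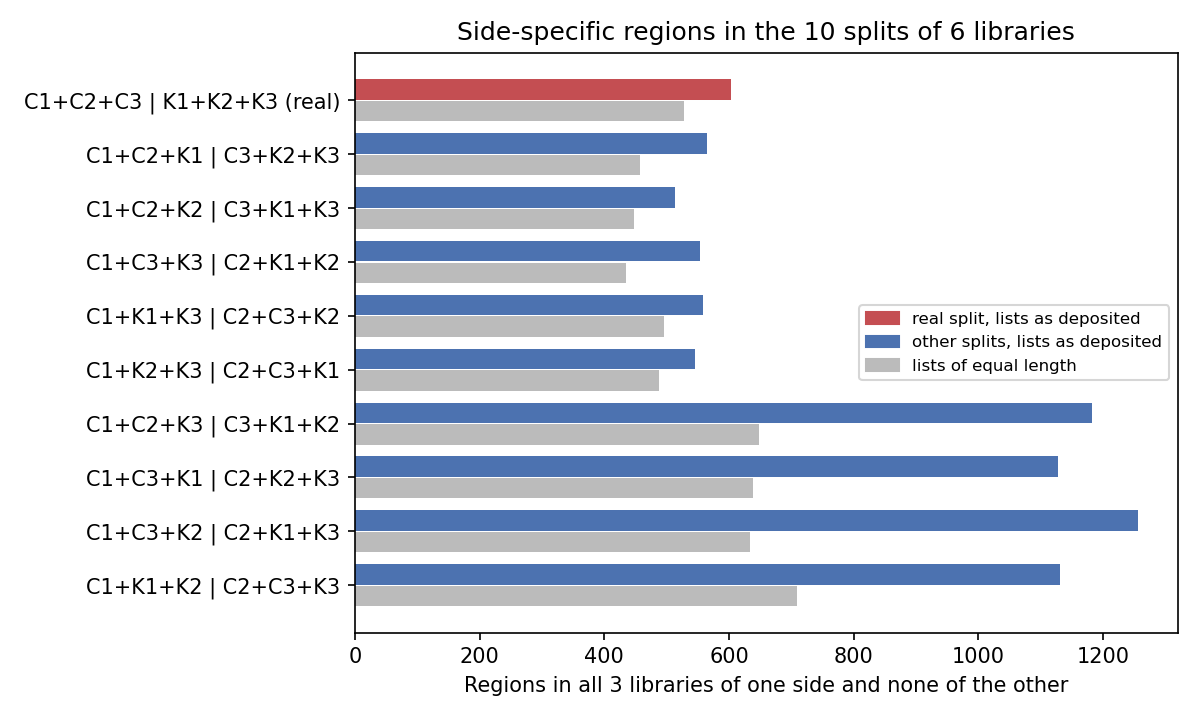
Regions present in all 3 libraries of one side and in none of the other (horizontal axis, number of regions) for each of the 10 divisions of the 6 libraries (C, control; K, knockdown; numbers are replicates), coloured bars for the lists as deposited and grey bars for lists of equal length. The real division gives 604 regions, the 5 others that part control replicate 2 from knockdown replicate 3 give 514 to 565, and the 4 that join them give 1128 to 1257.

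Among genes of the lists fixed for this cell type, group-specific regions were few and went both ways. Mylk, the kinase of the myosin light chain, carried a knockdown-only region inside the gene (chromosome 16, 34937569 to 34937987; fold enrichment 5.16 ± 0.806, SD, n = 3), and Casq2 a control-only region. Of the regulators, Notch3 and Prrx1 had a control-only region 14.5 kb below and 23.7 kb above the gene. Of the matrix genes, Col3a1 had a knockdown-only region 35.3 kb below the gene, and Col5a1 and Fbln2 a control-only region inside it. Mmp3, the matrix protease stromelysin-1, had a control-only region at its lower gene end (chromosome 9, 7445572 to 7445880; fold enrichment 5.80 ± 1.26, SD, n = 3). The chemokine genes Ccl5 and Cxcl12 had knockdown-only regions, Ccl5 inside the gene and Cxcl12 4.34 kb above it. In the TGF-β list, Smad7, an inhibitory Smad, had a knockdown-only region 30.3 kb below the gene (chromosome 18, 75336862 to 75337239; fold enrichment 7.39 ± 0.894, SD, n = 3). Smad2 had a knockdown-only region inside the gene, and Ccn2 had a control-only region 11.4 kb above. The endothelial marker Vwf had a knockdown-only region inside the gene. Of these 14 regions, that of Smad7 alone had a smallest −log10 q above 5, at 6.52. With lists of equal length, those of Mmp3 and Smad7 stayed group-specific and the other 12 were not.

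No list passed the test for more group-specific regions than other genes. Of 77250 regions assigned to a gene, 209 were control-only and 333 knockdown-only. So few were expected per list that a list with 0 could not pass as holding fewer, and only a large excess could pass. Over 38 Fisher's exact tests, two-sided, 0 had an adjusted p under 0.05 and 0 an unadjusted p under 0.05. The smallest unadjusted exact p was 0.103, for control-only regions of the smooth muscle regulators, at 2 of 200 regions (Notch3 and Prrx1; odds ratio 3.75, adjusted p = 1). Inflammation genes held 2 knockdown-only and 0 control-only regions among 172, and TGF-β genes 2 and 1 among 223. Contractile genes held 1 of each among 134 and collagen and synthetic matrix genes 1 of each among 231. Elastic fibre genes held 1 control-only region among 153, matrix proteases 1 among 98, and endothelial markers 1 knockdown-only region among 75. The lists of angiotensin and oxidant genes, cell cycle, apoptosis, AP-1, ARID family, housekeeping, and leukocyte, fibroblast, epithelial, neural and Schwann, and chondro-osteogenic markers held 0 in either direction.

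Group-specific gene ends included Csmd3, Mmp3, Pcdhb17, Lsg1, Igsf3, Fcer1g and Olfr222 on the control side and Acot12, Zfp688, Vldlr, Il15ra, Dgcr6, Mroh5, Edc3 and Adamts8 on the knockdown side. Fold enrichment at the gene end was 10.1 ± 3.33 for Zfp688, 7.09 ± 0.932 for Vldlr, a lipoprotein receptor gene, and 6.26 ± 0.0732 for the acyl-CoA thioesterase gene Acot12 in the knockdown libraries (SD, n = 3). It was 5.94 ± 1.05 for Csmd3 and 5.75 ± 1.33 for Fcer1g, which encodes an Fc receptor subunit and stood in the leukocyte list, in the control libraries (SD, n = 3). The only region assigned to Fcer1g was present in 6 of 6 libraries, so no control-only region was assigned to this gene. The smallest −log10 q was highest for Acot12 (6.25), Zfp688 (5.98) and Vldlr (5.75), while that of the 7 control-side genes named here ran from 2.75 to 3.94. For Csmd3, Mmp3, Lsg1, Fcer1g and Olfr222 it was the value of control replicate 2, the shallowest library. For Zfp688 and Vldlr it was that of knockdown replicate 3, the shallowest of its group. The smallest values therefore depend on depth and do not rank the 2 sides. There were 20 control-only and 36 knockdown-only gene ends, 56 together, and 6 of the 10 divisions of the libraries gave at least 56. With lists of equal length there were 41 control-only and 31 knockdown-only gene ends, so the excess turned round. It also did so without control replicate 2 (100 and 49), without knockdown replicate 2 (84 and 71) and in the 4 deepest libraries (140 and 134). Without knockdown replicate 1 there were 67 of each. The excess stayed without knockdown replicate 3 (37 and 97), control replicate 1 (42 and 102) and control replicate 3 (40 and 100).

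Within each library, the lists differed in how many members had an open gene end. Of the TGF-β genes, 13 of 18 had a gene-end peak in 6 of 6 libraries, among them Tgfb3, Tgfbr1 and Tgfbr2, against 36.4% of all genes (odds ratio 4.54, two-sided Fisher's exact test, p adjusted over the 19 lists 0.0352). Of the endothelial and of the epithelial markers, 0 of 12 did (adjusted p = 0.0352 for each by the same Fisher's exact test). Housekeeping genes had 8 of 12 and apoptosis genes, such as Bax, Bak1 and Bcl2l11, 11 of 18, with an adjusted p of 0.159 each. Contractile genes had 7 of 18, and Myh11 and Des, for smooth muscle myosin and desmin, had a gene-end peak in 0 of 6 libraries. Among regulators 6 of 18 had a gene-end peak in 6 of 6 libraries, including Mrtfa, while Srf and Gata4 had none in any library. Of regions assigned to these genes, however, 2 of 2 for Srf and 0 of 8 for Gata4 were present in 6 of 6 libraries. Collagen and synthetic matrix genes had 9 of 18 (Col1a1, Col1a2 and Col5a1), elastic fibre genes 7 of 16 (Fbn1, Fbln2), and matrix proteases and inhibitors 4 of 18 (Adamts4, Adamts5), with Mmp9 in 0 of 6 libraries. Of 20 inflammation genes, 10 had a gene-end peak in 6 of 6 libraries, among them the cytokine genes Il6 and Ccl2. Il1b had one in 0 of 6, though 1 of the 5 regions assigned to it was present in 6 of 6. Angiotensin and oxidant genes had 3 of 20, with Agtr1b, Agtr2 and Agt in 0 of 6 libraries. Cell cycle genes had 10 of 20 (Ccne2, Ccna2, Ccnb1), AP-1 genes 7 of 13 (Fos, Fosl2, Jun) and ARID family genes 6 of 14 (Arid3c, Arid1a, Arid4a). The only region assigned to Arid3c was not present in 6 of 6 libraries, so some of its gene-end peaks lay in regions assigned to another gene. Leukocyte markers had 2 of 12, and fibroblast, neural and Schwann, and chondro-osteogenic markers had 1 of 12, 1 of 12 and 1 of 10, with Ptprc, Pdgfra, Sox10 and Acan in 0 of 6 libraries. Of regions assigned to Pdgfra, however, 3 of 7 were present in 6 of 6 libraries. For Ptprc, Sox10 and Acan these were 0 of 7, 0 of 3 and 0 of 1.

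Between the groups, no list passed the test for its number of open members. Contractile genes had a gene-end peak for 9.67 ± 2.31 of 18 members in control and 10.7 ± 0.577 in knockdown libraries, and smooth muscle regulators for 9.33 ± 2.08 and 10.7 ± 0.577 of 18 (SD, n = 3). The collagen and synthetic matrix list had 13 ± 1.0 and 14.3 ± 1.15 of 18 (SD, n = 3; exact two-sided permutation p = 0.3), the elastic fibre list 9.33 ± 2.31 and 11.3 ± 0.577 of 16 (SD, n = 3; exact two-sided permutation p = 0.4). Leukocyte markers had 4.33 ± 1.15 in control and 3 ± 1.0 in knockdown libraries of 12 (SD, n = 3; exact two-sided permutation p = 0.3). ARID family genes had 11.7 ± 2.31 and 10.3 ± 1.53 of 14, and matrix proteases and inhibitors 10.7 ± 3.51 and 10 ± 2.0 of 18 (SD, n = 3). Inflammation genes had 13.3 ± 1.15 and 14.3 ± 0.577 of 20, and TGF-β genes 15.3 ± 0.577 and 14.7 ± 0.577 of 18 (SD, n = 3). Over the 19 lists, 0.3 was the smallest exact two-sided permutation p and each adjusted p was 1. Control replicate 2, the shallowest library, had the lowest count of its group in contractile genes (7 of 18), regulators (7 of 18) and cell cycle genes (12 of 20).

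**Figure D4:**
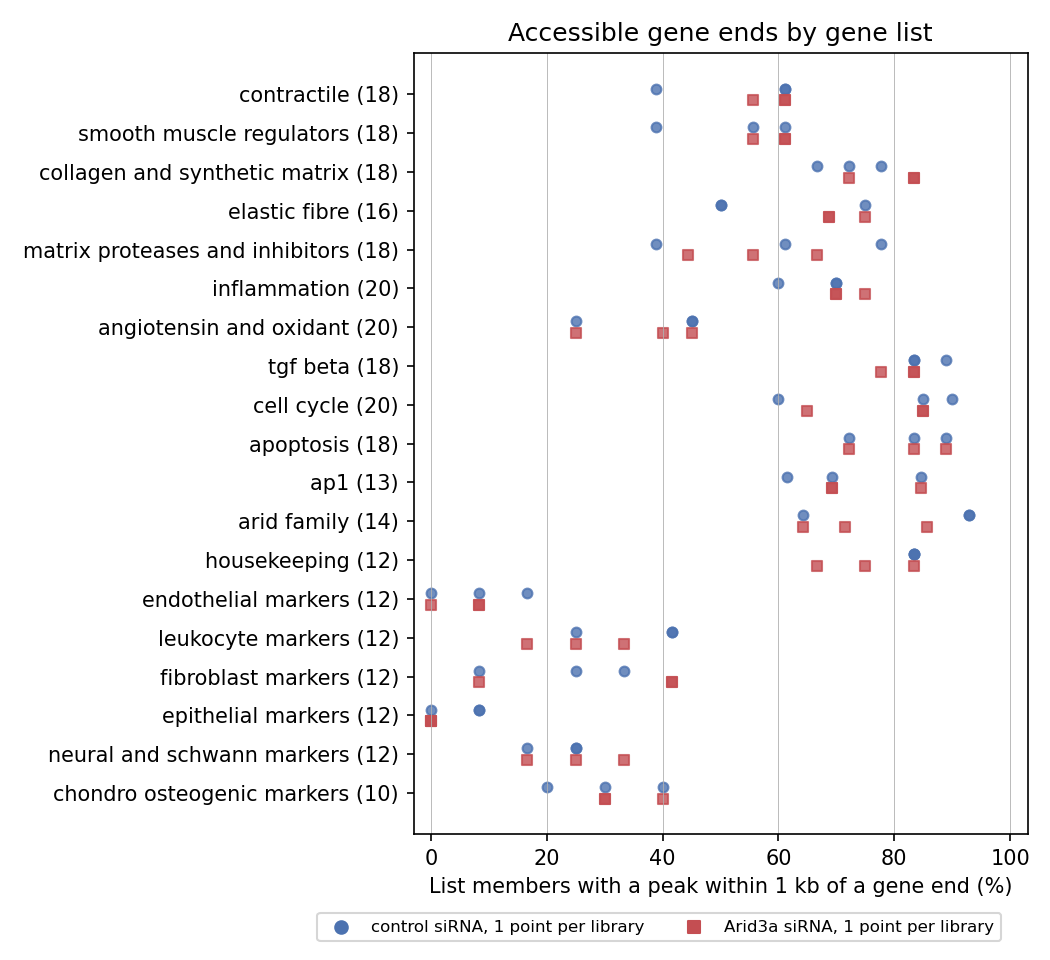
Percent of the members of each gene list with a peak within 1 kb of a gene end (horizontal axis), 1 point per library, blue circles for the negative control and red squares for Arid3a siRNA, with the number of members in brackets. The ranges of both groups meet or overlap in each of the 19 lists, and endothelial markers (0 to 2 of 12) and epithelial markers (0 to 1 of 12) lie lowest.

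The mean similarity of open chromatin was not higher within groups than between them. The mean Jaccard index was 0.453 within groups and 0.459 between groups, a difference of −0.00620 (exact one-sided permutation p = 0.5 over 10 divisions of the libraries). Pairs ranged from 0.399 to 0.514. With lists of equal length the means were 0.495 and 0.497 (difference −0.00212, exact one-sided permutation p = 0.5). Among the 6 divisions that part control replicate 2 from knockdown replicate 3, the shallowest libraries, the real one had the highest difference, −0.00620 against −0.00789 to −0.00629, and with lists of equal length −0.00212 against −0.00506 to −0.00312. The difference turned positive without control replicate 1 (0.00607) and without control replicate 3 (0.00537).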

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

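The comparison of the 4 deepest libraries and all alternatives for gene ends were chosen after the data were examined. Differences are knockdown minus control. The difference in peaks per library (2260.67) ran from −3893.5 to 5528 with 1 library left out, the lowest value being that without control replicate 2, and was −799.5 in the 4 deepest libraries. The difference in covered length (0.185 Mb) ran from −2.26, again without control replicate 2, to 1.74 Mb, and was also negative without knockdown replicate 1 (−0.223) and 2 (−0.639). It was −0.279 Mb with lists of equal length and −1.03 Mb in the 4 deepest libraries. The gene-end share (−0.821 percentage points) ran from −1.58 to 0.548, the highest value without control replicate 2, and was 0.285 in the 4 deepest libraries. The within-group minus between-group similarity ran from −0.0186 to 0.00607 with 1 library left out and was 0.00193 in the 4 deepest. The cause of these changes of sign was not tested beyond the libraries named, and no exact p can fall below 0.1 in any of these settings. Control-only regions numbered 75 at a −log10 q of 5 or more, 1166 when 1 of 3 libraries was allowed in the other group, and 2072 in the 4 deepest libraries; knockdown-only regions numbered 170, 1831 and 1870. With 1 library left out the counts were 391 to 1564 (highest without control replicate 2) and 475 to 1562 (highest without knockdown replicate 3). Fewer libraries then had to agree, which raises such counts by construction. Control-only gene ends numbered 41 with lists of equal length (against 31 knockdown-only), 140 in the 4 deepest libraries and 37 to 100 with 1 library left out. Knockdown-only gene ends numbered 17 at a −log10 q of 5 or more, 134 in the 4 deepest libraries and 49 to 102 with 1 library left out. The other settings kept both region counts within 1.5 times. The number of gene lists called was 0 in each of the 11 alternatives. The closest was inflammation genes without control replicate 3, with 7 knockdown-only regions among 157 (odds ratio 3.57, two-sided Fisher's exact p = 0.00463, adjusted p = 0.176, against 1 for the best list of each other alternative). Of 19 named regions per direction, 12 control-only and 13 knockdown-only regions stayed so with lists of equal length, 15 and 18 with 50% coverage, and 11 and 13 at a −log10 q of 5 or more. The last counts only restate how many had a smallest −log10 q of 5 or more, the value by which the rule ranked them. Lists of equal length also kept peaks by −log10 q. Whether replicate numbers pair the samples could not be told. Same-numbered libraries deviated together with correlations of 0.0180, −0.0354 and −0.0324 for replicates 1 to 3. For replicates 2 and 3 the pair joins a shallow library with a deeper one, and other such pairs had −0.0334 and −0.0321. Other cross-group pairs of the deepest libraries had 0.0154 to 0.0191, so the check cannot separate pairing from depth. With the replicate number as a block the differences were still 2260.67 peaks, 0.185 Mb and −0.821 percentage points, with an exact two-sided permutation p of 1 for each, where 0.25 is the smallest possible. Adding sequences outside chromosomes 1 to 19, X and Y changed nothing, since the lists hold none. The promoter window in its planned form and the motif comparison were not run. Depth limits what a list can hold, since 8 to 11 tags lay at the summit of a median peak and absence from a list does not show closed chromatin.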

Other observations

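The tests of depth, of a shared batch and of detection near the threshold, the grouping of divisions by the shallowest libraries, and the genes of the next paragraph were chosen after the results were seen.

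Outside the regions named so far, 8 genes of the fixed lists had a gene-end peak in 2 more libraries of one group than of the other. Myocd, the coactivator of smooth muscle genes, the elastic fibre genes Fbln1 and Ltbp4, and the adhesion molecule gene Vcam1 had one in 1 of 3 control and 3 of 3 knockdown libraries. Actb, Krt19 and the histone demethylase gene Kdm5b had one in 2 of 3 control and 0 of 3 knockdown libraries, and Kdm5c in 3 of 3 and 1 of 3. Together with Mmp3 and Fcer1g, with a gene-end peak in 3 of 3 control and 0 of 3 knockdown libraries, 10 of 290 list genes differed by at least 2 libraries at their gene ends. The other 9 divisions of the 6 libraries into 3 and 3 gave 7 to 21 such genes, and 8 of the 10 divisions gave at least 10.

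The divisions of the 6 libraries are too few for a share under 0.05. For group-specific regions, 5 of 10 divisions gave at least the 604 of the real one, and the highest other gave 1257. For group-specific gene ends, 6 of 10 gave at least 56, and the highest other gave 109. For gene lists called, the real count was 0, so that 10 of 10 divisions give at least as many by construction, and the highest other was 0.

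The 4 divisions that join control replicate 2 and knockdown replicate 3 gave 2.11 times as many group-specific regions as the 6 that part them. Sequencing depth may account for part of the pattern, because these are the shallowest libraries of the 6 and the ratio was 1.38 with lists of equal length. A shared batch of these 2 libraries cannot be told apart from depth: at equal list length their Jaccard index was 0.426, below the mean of 0.441 that control replicate 2 had with the other 4, but lists of low depth may share less whatever their batch. Their deviations also had the highest correlation of the 9 cross-group pairs, 0.0646 against −0.0354 to 0.0191. The ratio left at equal length stays open, and no biological explanation was tested, since the labels give these 2 libraries nothing in common.

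Among the 6 divisions that part these 2 libraries, the real one had the most group-specific regions, 604 against a mean of 547.2 ± 19.9 (SD, n = 5) for the other 5, and with lists of equal length 528 against 435 to 496. An effect of Arid3a knockdown on a small set of regions might give this. In the 4 deepest libraries, the real division of 2 against 2 also had the most of the 3 divisions, 3942 regions against 3776 and 3717. Among regions with a −log10 q of 5 or more in all 3 libraries of a side, 5 of the 6 divisions gave at least the 57 of the real one, and the highest other gave 64. With 3 and 6 divisions, Arid3a knockdown and chance cannot be told apart for these libraries.

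Group-specific regions rested on weak peaks, with a median percentile of 27.5 within their own lists. Regions specific to a side in the other 5 divisions that part the shallowest libraries had 25.7 to 28.1, so the peaks of the real division were about as weak as those that arbitrary groupings gave. Detection near the threshold may therefore decide the presence of many of these regions. A real loss or gain of accessibility at a subset of them would move such a median little and stays open.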
